A study of Mus musculus with 32 samples.

How the data were processed

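Nascent transcription was measured by PRO-seq, a nuclear run-on assay that maps engaged RNA polymerase with a biotinylated nucleotide, in 10 libraries, and polyadenylated RNA by strand-specific mRNA-seq in 22 libraries. All came from TX1072 cells, a female F1 hybrid mouse embryonic stem cell line of C57BL/6 (B6) and CAST/EiJ (Cast) parents in which 1 µg/ml doxycycline switches on Xist from the B6 X chromosome. The courses were PRO-seq of undifferentiated cells, mRNA-seq of undifferentiated cells and mRNA-seq of cells placed in differentiation conditions. The series text and the labels give duplicates for every RNA time point, while the treatment protocol names duplicates only at 0 and 24 h of the undifferentiated course. No label says that replicates came from separate cultures, so every p-value measures only the spread between these samples, which may be technical.

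The deposited PRO-seq table gives read counts of the B6 allele, the Cast allele and their sum, the fraction of allele-assigned reads that carried the B6 allele, and RPKM. The sum equalled B6 plus Cast in all 213234 gene and library values, and the deposited fraction equalled the ratio of the counts within 1e-05 in as many. The mRNA-seq tables deposited by the authors give RPKM and the B6 fraction but no counts, so the depth behind each RNA fraction is unknown and no interval is given for it. The authors name cutadapt 1.8.2, Bowtie 1.0.0, TopHat2 2.1.0, SAMtools and HTSeq 0.6.1 and the mm10 genome build; the role of each tool is not given in the sources used here. How reads were divided between alleles is not given in the sources used here either. PRO-seq start positions count from 0 (of 20833 genes matched to RefSeq by symbol, 6853 started 1 base lower than in RefSeq and 581 at the same base), and 1 was added to the starts printed.

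The PRO-seq libraries held 3041199 to 6443286 allele-assigned reads. The number of reads behind the RPKM scaling was estimated from the steps of the values (whole reads within 0.002). It was 4283273 to 9325875 in PRO-seq, 55353472 to 84038628 in undifferentiated mRNA-seq and 58964334 to 98356799 in differentiating mRNA-seq. The estimate is rough. In PRO-seq at 24 h replicate B, 3270 of 10123 genes checked gave whole reads, and the 6326175 reads estimated were fewer than the 6443286 allele-assigned reads. Intervals for single libraries are 95% Wilson intervals. Reads carry no molecular identifiers, so the intervals cover counting error only.

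The design, the gene lists, the naming rule and most alternatives were fixed before the data were examined. That design planned read counts for every assay. Since the RNA tables hold no counts, the planned edgeR tests of RNA were replaced by limma with the same groups and contrasts, a choice made after the data were seen. PRO-seq was tested with edgeR 4.0.16 (quasi-likelihood, robust). The allelic model had terms for library, allele and allele by group, for genes with a mean of at least 20 allele reads; the total model used TMM and filterByExpr. RNA was tested with limma 3.58.1 (trend, robust). The allelic RNA model used the log2 odds of the B6 share with a pseudocount of 0.01, which sets the size of a change from or to a share near 0 or 100%, for genes with a mean RPKM of at least 1 and a share in every library compared. The total RNA model used log2(RPKM + 0.5), for genes with a mean RPKM of at least 0.5, so the fold of a gene near 0 depends on that pseudocount. Each model held all libraries of its course, so that in RNA every time point set the spread. In PRO-seq the time points with a single library left no residual, so the spread came from the pairs at 0 and 24 h. The difference between courses was the interaction of time and course with all 22 RNA libraries. P-values were adjusted by Benjamini-Hochberg over all genes tested, with a threshold of 0.05; the tests are two-sided. The RNA comparison between courses follows the title prefixes of the libraries, so batch and differentiation state cannot be separated. Gene lists were tested with camera at a preset correlation of 0.01 and again with an estimated correlation.

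The 20 lists were naive, core, and formative and primed pluripotency; primitive streak and mesendoderm, neuroectoderm, primitive endoderm, trophectoderm, the two-cell-like state, and fibroblast or feeder markers; ERK and Wnt targets; the integrated stress response; p53 targets; DNA methylation; Xist partners; the X-inactivation centre; known mouse escape genes; X-linked pluripotency or signalling genes; X-linked constitutive genes; and mitochondrially encoded proteins, of which 0 of 13 members were in the tables, so that this list gave no result. Some members are shared between lists.

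Genes were named by rule. For total RNA these were the 10 largest changes in each direction past the threshold, with a mean log2 level of at least 3 and no overlap between the replicates of the groups. For allelic comparisons they were the 10 X-linked genes with the largest fall and the 10 with the smallest change, at a mean of at least 100 allele reads or an RPKM of at least 5, and up to 5 autosomal genes in each direction (10 for the difference between courses). For half-times they were the 8 shortest and 8 longest among X-linked genes with a rate above 3 times its SE and a mean of at least 100 allele reads or an RPKM of at least 5. Members of the lists were named as examples.

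The half-time of a gene is ln 2 divided by the rate at which its log odds of B6 fell with hours of doxycycline, that is the time for the B6:Cast ratio to fall to 50% of its value. It came from a quasi-binomial logistic regression on reads (PRO-seq) or least squares on log odds (RNA), for X-linked genes with a B6 share between 0.2 and 0.8 at 0 h. The X share of a library is the median B6 share over X-linked genes without Xist, and its change was set against 10000 random lists of autosomal genes matched on level. Correlations across genes used 100000 permutations. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3, were used. The models were also tested on simulated data with effects of known size.

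Replicates of the undifferentiated RNA course shared a series: the residuals of the 2 series correlated in all 15 pairs of time points, with r of 0.34 to 0.93 for total RNA and 0.13 to 0.26 for the B6:Cast ratio. Values with the series as a block are given beside most counts that moved by more than 1.5 times with it. In the differentiating course r was -0.29 to 0.41 for total RNA, over 0.1 in 5 of 10 pairs, and -0.071 to 0.046 for the B6:Cast ratio. Residuals there did not pair as consistently. PRO-seq had only 1 pair of time points, with r of 0.029 and 0.071. The 2 h replicate 1 library of the undifferentiated RNA course stood apart in total RNA: its log2 RPKM correlated with the other 2 h replicate at r = 0.855, against 0.968 to 0.983 for the other undifferentiated pairs and 0.998 to 0.999 for the differentiating pairs. It was kept, and results without it are given where they differ. Alternatives covered the filter on low values, the scaling, pseudocounts, DESeq2 1.42.0 on PRO-seq counts, each replicate left out in turn, the 2 compared groups alone, and replicate blocks. Those added after seeing the data were the pseudocounts, limma on PRO-seq RPKM, the fits without 2 h replicate 1, the blocks for the difference between courses, and each left-out replicate for the X share. A few genes that met the rule for naming are not reported here; they are kept in the counts and list tests.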

Results

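The data cover 32 libraries of TX1072 cells. PRO-seq of undifferentiated cells was done at 0 and 24 h of doxycycline in 2 libraries each and at 0.5, 1, 2, 4, 8 and 12 h in single libraries, which have no replicates. Undifferentiated mRNA-seq covers 0, 2, 4, 8, 12 and 24 h, and mRNA-seq of differentiating cells 0, 8, 16, 24 and 48 h, with 2 libraries per time point. The tables list 26440, 13888 and 15012 genes, of which 902, 514 and 541 are X-linked. Depth was 3041199 to 6443286 allele-assigned reads in PRO-seq. For RNA there is only the rough estimate from the RPKM steps, 55353472 to 84038628 reads in undifferentiated and 58964334 to 98356799 in differentiating libraries. The study asks which features make X-linked genes easy or hard for Xist to silence, and what differentiation changes. All positions are on mm10.

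Xist, the non-coding RNA that coats and silences the chromosome it is made from (X, 103460375 to 103483217), appeared within the first hour of doxycycline. Its nascent level was 0.157 ± 0.049 RPKM (SD, n = 2) at 0 h, 0.771 at 0.5 h, 3.7 at 1 h, 14.1 at 2 h and 30.7 at 4 h, and 28.5 ± 2.48 (SD, n = 2) at 24 h. At 0.5 h, 5 of 8 allele-assigned Xist reads were B6 (62.5%, 95% Wilson interval 30.6 to 86.3); at 1 h, 40 of 40 were (100%, interval 91.2 to 100). At 24 h B6 gave 358 of 363 reads in replicate A and 709 of 711 in replicate B. Xist RNA in undifferentiated cells rose from 0.050 ± 0.0090 RPKM at 0 h to 11.3 ± 1.54 at 4 h and 38.8 ± 10.0 at 24 h (SD, n = 2). In differentiating cells it was 36.8 ± 2.36 RPKM at 8 h, 52.1 ± 9.67 at 16 h and 33.5 ± 0.14 at 48 h (SD, n = 2).

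The B6 share of X-linked genes fell after Xist appeared, in nascent and in mature RNA. The median B6 share of nascent transcription over 349 X-linked genes other than Xist was 49.7% ± 0.73 (SD, n = 2) at 0 h, 48.8% at 2 h, 47.7% at 4 h, 39.3% at 8 h, 34.8% at 12 h and 30.4% ± 0.10 at 24 h. In undifferentiated RNA it was 50.5% ± 0.20 at 0 h, 49.6% ± 0.17 at 4 h, 45.5% ± 3.18 at 8 h, 40.7% ± 4.60 at 12 h and 32.3% ± 6.48 at 24 h (SD, n = 2, 290 genes). In differentiating RNA it was 49.9% ± 0.059 at 0 h, 42.0% ± 0.24 at 8 h, 31.2% ± 0.043 at 16 h, 26.3% ± 0.19 at 24 h and 25.2% ± 0.62 at 48 h (SD, n = 2, 285 genes). The autosomal median stayed between 50.8 and 51.8% in every group. From 8 h on, 0 of 10000 random autosomal lists matched on level changed as far down as the X-linked genes in any library of the 3 courses. At 4 h of PRO-seq 5 did. The wide spread in undifferentiated RNA at 24 h came from the pair of series, with a median X share of 27.8% in replicate 1 and 36.9% in replicate 2.

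**Figure D1:**
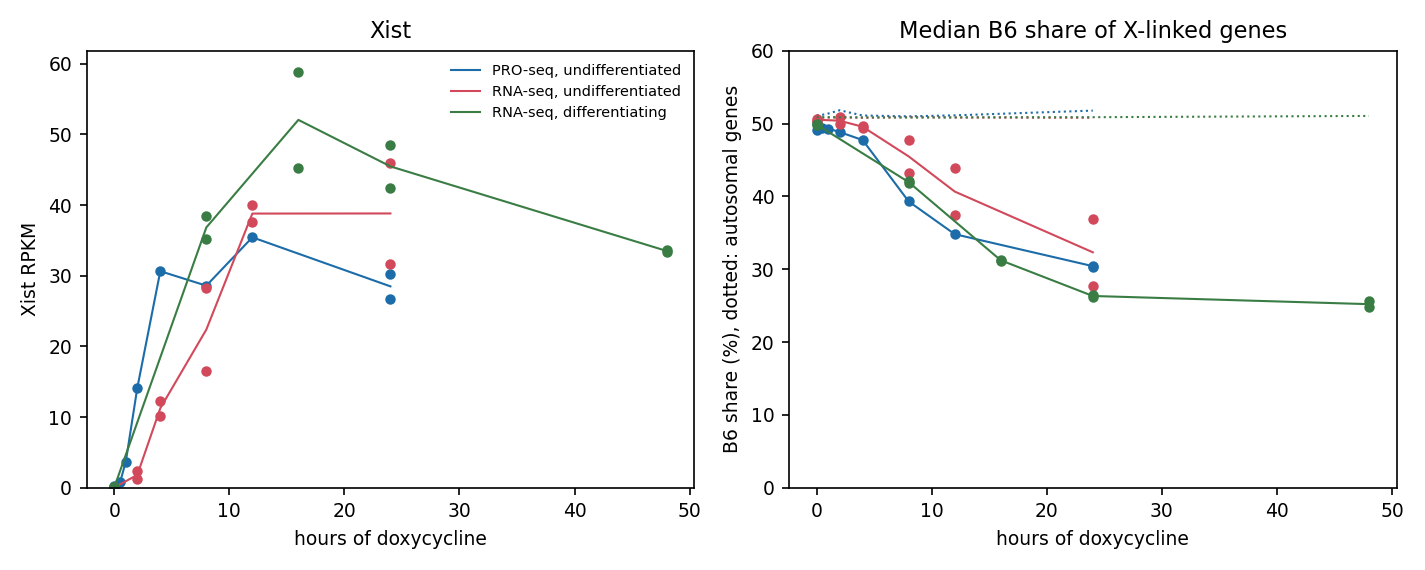
Xist RPKM and the median B6 share of X-linked genes (percent) against hours of doxycycline in the 3 courses; points are libraries, lines join means, and dotted lines are autosomal medians. Autosomes stay between 50.8 and 51.8%, while the X median reaches 30.4% in PRO-seq at 24 h and 25.2% in differentiating RNA at 48 h.

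Nascent transcription at 24 h was compared with 0 h to find which genes fell in B6 share after Xist was induced. Stard8, which encodes a GTPase-activating protein (99003248 to 99074728), fell most: its B6 share went from 37.2% ± 7.64 to 5.51% ± 0.92 (SD, n = 2), a log2 change in B6:Cast of -3.25 (SE 0.39, edgeR adjusted p = 2.8e-06). Klf8, a Krüppel-like transcription factor (153237466 to 153396132), went from 49.2 to 14.8% (-2.47, SE 0.25), and the long non-coding RNA gene Firre (50555744 to 50635321) from 48.8 to 16.4% (-2.29, SE 0.14, edgeR adjusted p = 1.9e-12). Rlim, the ubiquitin ligase gene that activates Xist (103957163 to 103981284), went from 50.7% ± 0.73 to 17.2% ± 1.05 (SD, n = 2, -2.28, SE 0.35, edgeR adjusted p = 0.00016). At the other end, the histone demethylase gene Kdm6a, a known escape gene (18162575 to 18279936), was at 51.0% ± 2.99 and 48.6% ± 2.49 (SD, n = 2, -0.16, SE 0.18, edgeR adjusted p = 0.97). The isocitrate dehydrogenase subunit gene Idh3g (-0.09, SE 0.26), the RNA helicase gene Ddx3x (-0.17, SE 0.22) and Brcc3, Tbc1d25, Msl3, Gm14820, Atp6ap2, Yipf6 and 1810030O07Rik (-0.15 to -0.25) also did not pass.

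Of 350 X-linked genes tested, 105 fell and 0 rose (241 lower and 0 higher at unadjusted p under 0.05; DESeq2 30 lower and 0 higher), 229 fell when adjusted over the X alone, and the median X-linked change was -1.14 (2.21-fold lower). Of 13042 autosomal genes, 3 fell and 5 rose. Of 14 measured constitutive X-linked genes 10 fell (13 adjusted over the list alone), among them the chromatin remodeller Atrx (50.2 to 28.6%, -1.33, SE 0.13), the purine salvage gene Hprt (54.9 to 33.7%, -1.28, SE 0.24) and the glycolytic gene Pgk1 (-1.90, SE 0.23). Of 9 X-linked pluripotency or signalling genes 6 fell (7 adjusted over the list alone), including the nuclear receptor gene Nr0b1 (-2.37, SE 0.47) and Fhl1 (-2.19, SE 0.30). Of 13 known escape genes 2 fell, Shroom2 (-1.16, SE 0.24) and the deubiquitinase gene Usp9x (-0.55, SE 0.13), and 7 did so adjusted over the list alone. Escape genes as a group had a median of -0.68 against -1.16 for 336 others, a difference of 0.48 (two-sided permutation p = 0.02), with 12 of 13 above the median of the others. Of 5 X-inactivation centre genes, Rlim and Tsix fell (3 adjusted over the list alone); Tsix (-0.70, SE 0.16) is antisense to Xist and overlaps it, so its reads are uncertain. Of the remaining lists only naive pluripotency had a member past the threshold over all genes, the X-linked Nr0b1. Adjusted over the list alone, p53 targets had 1 member higher (Bax) and 1 lower (the X-linked Eda2r), and Xist partners 1 higher (Matr3).

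The 8 autosomal calls included 4930445N18Rik (-1.60), Rilpl1 (-1.09), Uggt2 (1.71), Zfp740 (1.56), Nupr1 (1.43), Gm12298 (1.05) and 2610037D02Rik (0.59). The number of X-linked genes that fell depended on having both replicates: it was 41 without 0 h replicate A, 48 without 0 h replicate B, 42 without 24 h replicate A and 28 without 24 h replicate B, all of them among the 105. Rlim itself did not pass without 24 h replicate B (-2.37, edgeR adjusted p = 0.10). Autosomal calls were 0 by edgeR without 0 h replicate A or either 24 h replicate (627 to 671 of all genes at unadjusted p under 0.05), and 11 lower and 19 higher without 0 h replicate B.

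Mature RNA of undifferentiated cells at 24 h showed the same direction. Nr0b1, an X-linked regulator of the pluripotent state (86191764 to 86195947), went from 50.8% B6 ± 1.64 to 12.2% ± 4.13 (SD, n = 2; log2 change -2.84, SE 0.34, limma adjusted p = 0.0086). Maged2 (-2.52, SE 0.26), the amino acid transporter gene Slc7a3 (-2.43, SE 0.31) and the actin-bundling gene Pls3 (53.2 to 20.6%, -2.10, SE 0.24) fell as well. Morf4l2 (-2.66, SE 0.56), Klf8 (-2.44, SE 0.53), Firre (86.3 to 52.8%, -2.42, SE 0.56), Tceal8 (-2.29, SE 0.45), Rlim (-2.25, SE 0.57) and Mageh1 (-2.11, SE 0.56) had changes as large but did not pass, with limma adjusted p from 0.071 to 0.21. Least changed were Ssr4 (0.06), Gm16411 (0.09), Nkap (-0.19), Haus7 (-0.19), Dkc1 (-0.23), the cold-shock gene Rbm3 (-0.28) and Klhl13 (-0.29), none past the threshold. Rbm3, however, passed with the replicate series as a block (limma adjusted p = 0.045). Gm16411 was at 99.0% B6 at 0 h and 99.1% at 24 h, so almost no Cast RNA was counted and its change says little about silencing. Idh3g fell slightly, from 51.0% ± 0.57 to 45.3% ± 0.57 (SD, n = 2, -0.32, SE 0.060, limma adjusted p = 0.048).

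Of 301 X-linked genes, 102 fell and 0 rose (262 lower and 0 higher at unadjusted p under 0.05 by limma), with 257 lower when adjusted over the X alone and a median of -1.10 (2.14-fold lower). Of 9843 autosomal genes 0 fell and 3 rose by limma (599 of all genes at unadjusted p under 0.05). Those that rose included Gm15443 (70.7 to 100% B6, a log2 change whose size of 5.42 is set by the pseudocount) and the RNA helicase gene Ddx28 (0.81). With the replicate series as a block 3 autosomal genes fell and 6 rose. Ddx28 did not pass without 0 h replicate 1 (limma adjusted p = 0.083), 0 h replicate 2 (0.17) or 24 h replicate 1 (0.14). Of 15 constitutive X-linked genes 8 fell (14 adjusted over the list alone), including Pdha1 (62.8 to 43.3%, -1.12, SE 0.070), G6pdx (-1.10, SE 0.11) and Hprt (58.2 to 43.7%, -0.83, SE 0.12). Of 10 X-linked pluripotency or signalling genes 5 fell (9 adjusted over the list alone), including Nr0b1. Of 11 escape genes 2 fell, Utp14a (-0.67, SE 0.096) and the creatine transporter gene Slc6a8 (-0.74, SE 0.14), and 7 did adjusted over the list alone; their median exceeded that of the other genes by 0.45 (two-sided permutation p = 0.062). Kdm6a was at 53 and 51.9%. Both X-inactivation centre genes measured, Rlim among them, fell when adjusted over the list alone and neither over all genes. Of the 14 naive pluripotency genes Nr0b1 alone fell, over all genes and adjusted over the list alone. Trophectoderm and Wnt genes had 1 member higher each, adjusted over the list alone. At 2, 4, 8 and 12 h limma called 0 genes (548, 293, 277 and 393 at unadjusted p under 0.05), with median X-linked changes of -0.0095, -0.046, -0.27 and -0.56.

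The undifferentiated count rested on single libraries. It was 4 without 0 h replicate 1, 10 without 0 h replicate 2, 27 without 24 h replicate 1, 159 without 24 h replicate 2 and 65 without 2 h replicate 1. With the 2 groups alone limma called 0 X-linked genes (546 genes at unadjusted p under 0.05), and it called 161 with the replicate series as a block, where Morf4l2, Klf8, Firre, Tceal8, Rlim, Mageh1 and Rbm3 passed too. Rlim and Mageh1 did not pass with the block and without 2 h replicate 1. Autosomal calls went from 1 lower and 1 higher without 0 h replicate 1 to 5 and 7 without 24 h replicate 2. Without 0 h replicate 1 or 2 Nr0b1 had limma adjusted p of 0.086 and 0.097, Maged2 0.077 and 0.054, Slc7a3 0.099 and 0.097, and Pls3 0.081 and 0.077. Without 24 h replicate 1 Nr0b1 had a limma adjusted p of 0.054 and Slc7a3 0.072. Idh3g did not pass without any 1 of these 5 libraries (0.070 to 0.35).

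Differentiating cells, in which doxycycline and differentiation started together, had a lower B6:Cast ratio of RNA for 265 of 285 X-linked genes at 48 h. Pls3 went from 51.9% B6 ± 0.028 to 8.82% ± 0.87 (SD, n = 2, -3.34, SE 0.099, limma adjusted p = 4.8e-07), and the actin cross-linker gene Flna (74223461 to 74249820) from 55.2 to 11% (-3.20, SE 0.056). Nr0b1 went from 50.6 to 10.7% (-2.98, SE 0.050, limma adjusted p = 4.4e-08). The other large falls were in 1700013H16Rik (-3.43), 4930502E18Rik (-3.37), Nup62cl (-3.21), Morf4l2 (-3.14), Tceal8 (-3.02), Gpc4 (-2.95) and Gm3880 (-2.90). Gm3880 went from 11.2 to 0.809% B6, so the pseudocount sets the size and rank of its change. Even the genes named as least changed, at a mean RPKM of at least 5, fell. Among them were Rbm3 (58.4 to 51.7%, -0.39, SE 0.048), Dkc1 (-0.56), Hccs (-0.69), Idh3g (51.0 to 38.5%, -0.72, SE 0.049), Prps1 (-0.72), Ftsj1 (-0.75) and Tbc1d25 (-0.76). Of all 285 X-linked genes 282 had a change below 0. Kdm6a, outside the named set, was 1 of those that did not pass: it was at 52.0% ± 0.35 and 52.1% ± 1.34 (SD, n = 2, 0.01, SE 0.093, limma adjusted p = 0.97). Rpl10 (-0.40, limma adjusted p = 0.052 without 48 h replicate 2), Pgk1 (-0.48) and Eif2s3x (-0.50) also stood among the least changed. The RNA share of Pgk1, however, was 0.445% at 0 h against 49.4% in PRO-seq, and that of Eif2s3x 14.2% against 44.5%, so the allele assignment of RNA of both genes is in doubt. The same holds for Firre, at 86.3% in undifferentiated RNA at 0 h against 48.8% in PRO-seq. Rpl10 began at 79.3% B6, and in undifferentiated RNA it was at 16.0 to 22.6 RPKM in 11 libraries but at 850 in 2 h replicate 1. Its small change is therefore uncertain too. Pgk1 and Eif2s3x are among the falls counted by list. With a share pseudocount of 0.05 the change of Pgk1 was -0.12 and did not pass (limma adjusted p = 0.053).

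By limma 0 X-linked genes rose, also at unadjusted p under 0.05, 275 fell adjusted over the X alone, and the median was -1.51 (2.84-fold lower), larger than the spread of 0.046 between replicates. The number that fell was 90 of 289 at 8 h, 235 of 289 at 16 h and 257 of 287 at 24 h, with medians of -0.40, -1.09 and -1.39. All 13 constitutive genes fell (13 adjusted over the list alone), for example Hprt (57.5 to 30.3%, -1.60, SE 0.058). All 8 X-linked pluripotency or signalling genes fell (8 adjusted over the list alone), with the MAP kinase phosphatase gene Dusp9 at -2.70 (SE 0.052) and Fhl1 at -2.81 (SE 0.12). All 3 X-inactivation centre genes fell (3 adjusted over the list alone): Tsx (-4.72, SE 0.65), Rlim (49.7 to 14.9%, -2.42, SE 0.076) and Chic1 (-2.09, SE 0.13). Of 10 escape genes 9 fell (9 adjusted over the list alone), including Slc6a8 (-1.58, SE 0.087), Usp9x (-1.36, SE 0.064) and Ddx3x (47.8 to 33.8%, -0.83, SE 0.046). The escape median exceeded that of 275 others by 0.47 (two-sided permutation p = 0.1). Autosomal genes changed in both directions, 1059 lower and 1149 higher of 10023 (758 higher without 48 h replicate 1). They were led by Ephx2 (-4.93), Nefm (-4.54), Nefl (-3.62), Wiz (-3.58) and Tcte2 (-3.49), and by Sytl3 (4.44), Optn (3.76), Gm16233 (3.7), Gramd3 (3.42) and Slc1a3 (2.51). Sytl3 began at 0.0845% B6 and Ephx2, Nefm and Wiz at 99.1 to 99.6%, so the pseudocount sets the size and order of their changes. The spans of Nefm and Nefl overlap, so their values are not separate evidence.

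**Figure D2:**
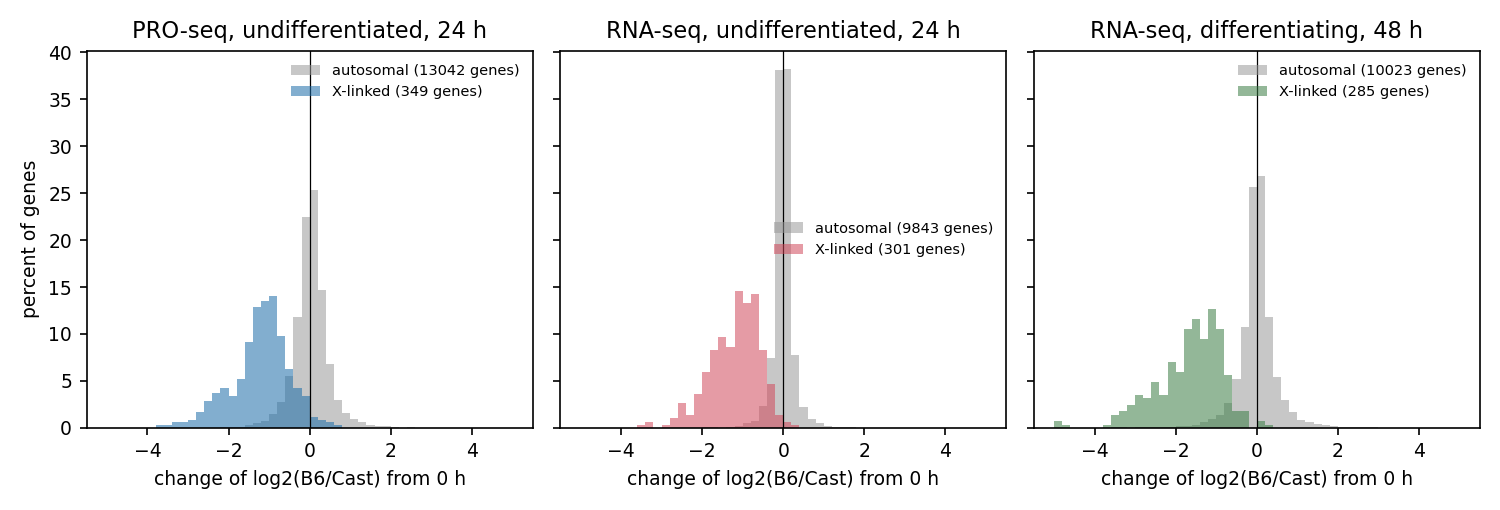
Histograms of the change in log2(B6/Cast) from 0 h for X-linked and autosomal genes in PRO-seq at 24 h, undifferentiated RNA at 24 h and differentiating RNA at 48 h; the vertical axis is percent of genes. X-linked medians lie at -1.10 to -1.51, with autosomes centred near 0.

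**Figure D3:**
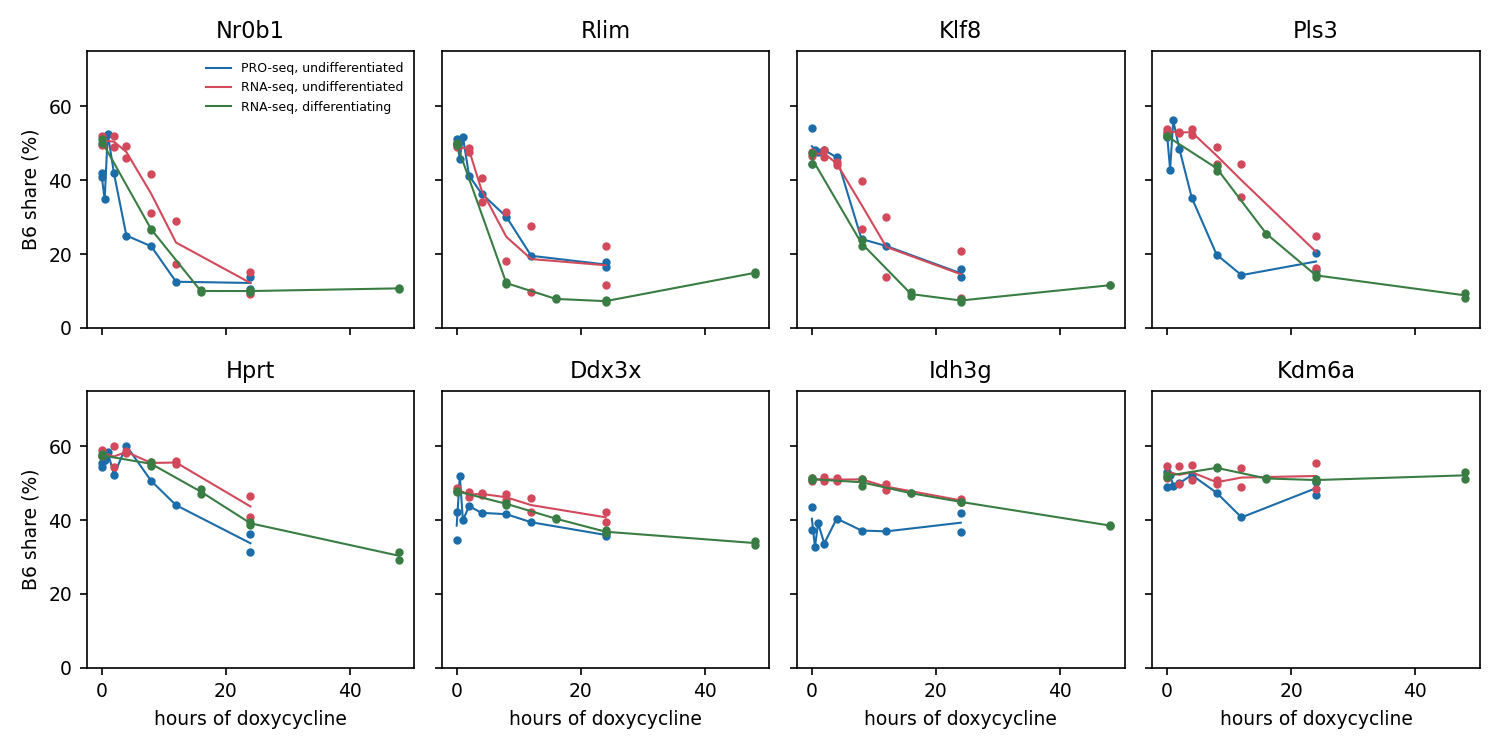
B6 share (percent) against hours of doxycycline for Nr0b1, Rlim, Klf8, Pls3, Hprt, Ddx3x, Idh3g and Kdm6a in the 3 courses; points are libraries and lines join means. In differentiating cells Nr0b1 ends at 10.7% and Kdm6a at 52.1%.

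Whether differentiation changed silencing was tested as the difference between the 24 h changes of the RNA courses. Ercc6l, which encodes a DNA helicase of mitotic chromosomes (102141716 to 102157091), fell further in differentiating cells: its B6 share went from 54.6% ± 1.72 to 18.9% ± 0.91 there and from 53.8% ± 1.31 to 40.1% ± 7.91 in undifferentiated cells (SD, n = 2, difference -1.52, SE 0.25, limma adjusted p = 0.0035). Klhl13, a gene that affects pluripotency and MAP kinase signalling, went to 34.8% against 41.7% (-0.53, SE 0.10, limma adjusted p = 0.0080). Lage3 (-0.76, SE 0.16), the prefoldin subunit gene Vbp1 (-0.57, SE 0.14) and Yipf6 (-0.82, SE 0.19), the last chosen after its values were seen, completed the 5 X-linked genes that fell further. Of 299 tested 0 fell less by limma (56 further and 4 less at unadjusted p under 0.05), 227 were below 0, and 3 fell further adjusted over the X alone. Rlim was at 7.25% in differentiating and 17% in undifferentiated cells (-1.24, SE 0.63, limma adjusted p = 0.38), and Kdm6a did not differ detectably (0.00, SE 0.21).

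The median X-linked difference was -0.31 against a spread of 0.39 between replicates, so a general difference in silencing was not detectable. Of the X-linked pluripotency or signalling genes 1 of 9 passed (Klhl13; 2 adjusted over the list alone). Of 10 escape genes and 15 constitutive genes 0 passed over all genes or adjusted over the list alone (limma, 1604 of 10118 genes at unadjusted p under 0.05). Of 7 core pluripotency genes 3 shifted toward B6 in differentiating cells and 4 did not pass (4 higher and 1 lower adjusted over the list alone), including Dppa5a (1.01, SE 0.11) and Lin28a (0.65, SE 0.15). Of 14 naive genes 2 rose and 2 fell (2 and 3 adjusted over the list alone), with the nuclear receptor gene Esrrb at -0.60 (SE 0.075). Across autosomes 169 genes were lower and 181 higher, led by Nefm (-4.62), Cyp2b23 (-3.56), Ephx2 (-3.54), 2310043M15Rik (-3.38), Pink1 (-2.65) and Fcgrt (-2.32) downward. Upward they were led by the autophagy receptor gene Optn (4.10, SE 0.21; 8.14 to 60.6% in differentiating and 11.2 to 10.1% in undifferentiated cells), Sytl3 (3.64), Pglyrp1 (2.76), Sirt5 (2.58), Cd276 (2.36) and Id1 (2.23). The pseudocount sets the sizes for Nefm, Ephx2 and Sytl3 here too.

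The X-linked count was 38 without undifferentiated 24 h replicate 1, 2 without 24 h replicate 2 of that course (with 4 falling less), 2 and 3 without differentiating 0 h replicate 1 and 2 and 3 without differentiating 24 h replicate 2. It was 8 without 2 h replicate 1 and 24 with the undifferentiated series as a block. The autosomal counts, lower and higher, were 117 and 108 without undifferentiated 0 h replicate 1, 105 and 86 without differentiating 0 h replicate 1, 109 and 102 without differentiating 0 h replicate 2, and 312 and 306 with the block. Lage3 did not pass without undifferentiated 0 h replicate 1, undifferentiated 24 h replicate 2, either differentiating 0 h replicate or differentiating 24 h replicate 2 (limma adjusted p 0.059 to 0.081). Vbp1 passed in only 2 of the 8 fits that left out a library compared. At 8 h 0 X-linked genes differed by limma (892 genes at unadjusted p under 0.05), with a median of -0.16.

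Half-times ranked the genes by the fitted rate of fall of B6:Cast over all hours covered, which need not be the order in which they were silenced. Those named had rates above 3 times their SE and passed a limit on level, so longer but less precise half-times, such as that of Kdm6a in PRO-seq (119 h, 71.3 to 358), are not among them. In nascent transcription the shortest was that of Stard8, 7.12 h (6.36 to 8.09 at ±1 SE of the rate), followed by Nhsl2 (7.59 h), Slc25a53 (8.02 h), Phka1 (8.90 h), Klf8 (8.96 h), Tmsb15b2 (9.02 h), Pls3 (9.06 h) and Pdk3 (9.24 h). The longest of this precision were those of Usp9x (43.6 h, 39.2 to 48.9), Otud5 (42.7 h), the O-GlcNAc transferase gene Ogt (42.6 h), Rab9 (41.1 h), Rbm3 (40.8 h), Uba1 (38.8 h), Cask (37.5 h) and Taf1 (36.1 h). In undifferentiated RNA the shortest was that of Nr0b1 (7.79 h, 7.05 to 8.70), then Morf4l2 (8.56 h), Klf8 (8.88 h), Maged2 (9.36 h), Slc7a3 (9.39 h), Tceal8 (9.45 h), Rlim (9.85 h) and Armcx1 (10.1 h). The longest of this precision were those of Dkc1 (124 h, 94.3 to 183), Rbm3 (76.6 h), Klhl13 (73.4 h), Idh3g (71.0 h), Ddx3x (56.8 h), Ftsj1 (56.5 h), Atp6ap2 (54.1 h) and Tbc1d25 (53.8 h). In differentiating RNA the shortest were those of 1700013H16Rik (13.5 h), 4930502E18Rik (13.7 h), Pls3 (13.8 h), Nup62cl (14.6 h), Flna (14.7 h), Morf4l2 (14.8 h), Tceal8 (16.8 h) and Gpc4 (16.9 h). The longest of this precision there were those of Tbc1d25 and Ftsj1 (61.1 h each), Idh3g (64.0 h), Zrsr2 (64.5 h), Eda2r (67.1 h), Mmgt1 (69.4 h), Dkc1 (80.4 h) and Rbm3 (117 h, 107 to 129).

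The median half-time was 19.8 h in PRO-seq (334 genes with a rate above 0 of 337, quartiles 14.3 and 29.4 h), 20.4 h in undifferentiated RNA (288 of 290; 13.7 and 30.8 h) and 32.4 h in differentiating RNA (276 genes, 23.2 and 45.0 h). Known escape genes had longer medians than the other genes, 34.4 against 19.7 h in PRO-seq, 35.4 against 19.9 h in undifferentiated RNA and 44.8 against 31.9 h in differentiating RNA, a difference not tested on this scale. X-linked pluripotency or signalling genes had a median of 17.7, 14.6 and 30.2 h in the same order, and constitutive genes 17.5, 21.4 and 33.5 h. The fit is a straight line in log odds, and the fall levelled off after 24 h in differentiating cells, so the value depends on the hours covered. The order of genes depends on them too. In differentiating RNA Nr0b1 was at 26.9 and 26.5% B6 at 8 h and at 10.9 and 10.5% at 48 h. Pls3 was at 42.5 and 43.9% at 8 h and at 9.44 and 8.20% at 48 h. Yet Pls3 was among the 8 shortest half-times named there and Nr0b1 was not. Without 48 h the median there was 16.3 h, and without 24 h that of PRO-seq was 12.6 h. The undifferentiated series gave 16.2 and 26.1 h when fitted alone.

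Genes with short half-times in 1 course tended to have short ones in the others. The RNA half-times describe the B6 share of mature RNA, whose turnover was not measured, so they are not rates of silencing alone. Across 229 genes, which are not independent replicates, PRO-seq and undifferentiated RNA half-times had a Spearman rho of 0.74 and a Pearson r of 0.69 on the log scale. The undifferentiated and differentiating RNA half-times had rho 0.67 and r 0.62 (265 genes), and PRO-seq and differentiating RNA rho 0.61 and r 0.52 (221 genes). Each had a two-sided permutation p = 1e-05, the smallest that 100000 permutations give, in a family of 9 relations (adjusted p = 1.8e-05 for rho and 2.2e-05 for r). Genes farther from Xist had longer half-times, with rho 0.36 and r 0.26 in undifferentiated RNA (286 genes, permutation p = 1e-05, adjusted 1.8e-05 and 2.2e-05). In differentiating RNA rho was 0.34 (275 genes, permutation p = 1e-05, adjusted 1.8e-05) and r 0.28 (permutation p = 2e-05, adjusted 3.6e-05). In PRO-seq rho was 0.23 (334 genes, permutation p = 2e-05, adjusted 3e-05) and r 0.11 (permutation p = 0.051, adjusted 0.065). The level at 0 h related weakly to half-time in PRO-seq (rho 0.11, permutation p = 0.037, adjusted 0.041; r 0.056, permutation p = 0.31, adjusted 0.34). In undifferentiated RNA rho was 0.14 (permutation p = 0.016, adjusted 0.02) and r 0.16 (permutation p = 0.0064, adjusted 0.0097). No relation was found in differentiating RNA (rho 0.03, permutation p = 0.65; r 0.016, permutation p = 0.8, both adjusted values the same). Without known escape genes neither rho passed (0.11 in PRO-seq, permutation p = 0.059, adjusted 0.067, and 0.12 in undifferentiated RNA, permutation p = 0.041, adjusted 0.052), while r still did in undifferentiated RNA (0.15, permutation p = 0.011, adjusted 0.016) and not in PRO-seq (0.048, permutation p = 0.39, adjusted 0.43).

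**Figure D4:**
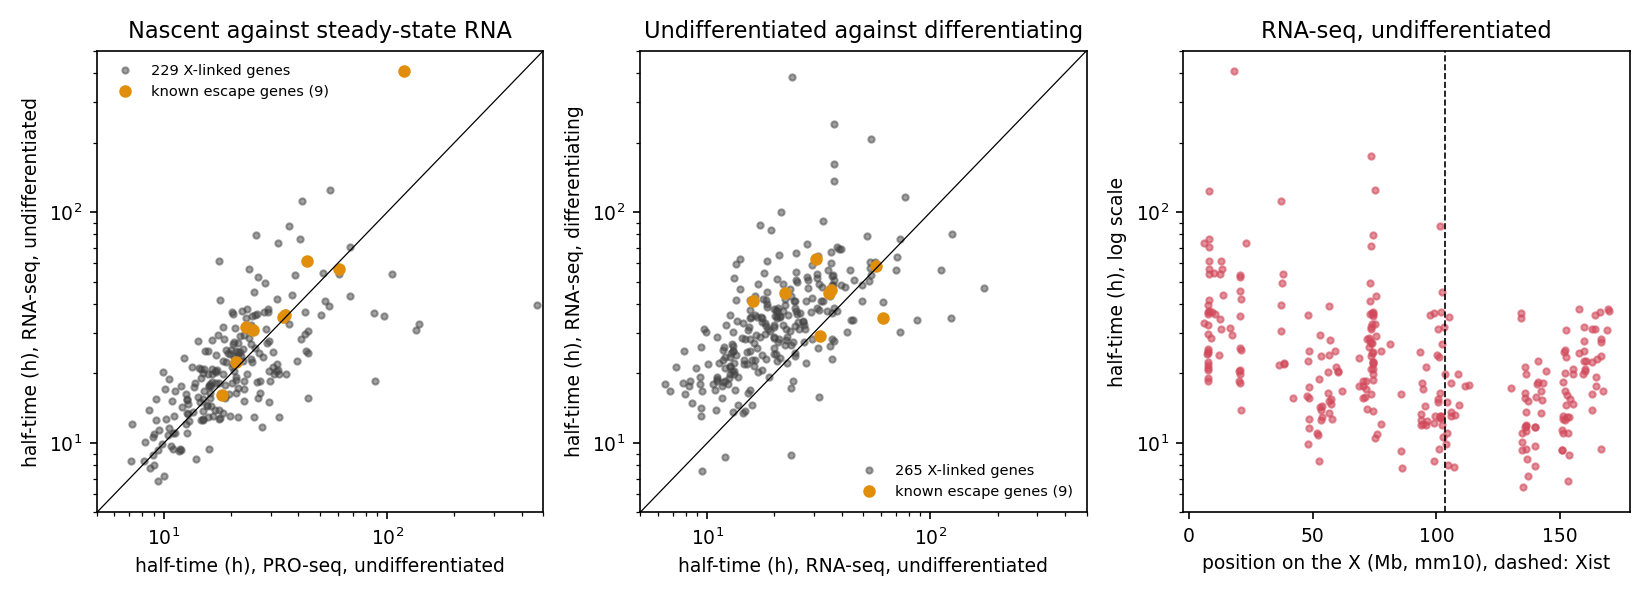
Half-times (hours, log axes) of X-linked genes in PRO-seq against undifferentiated RNA (229 genes) and in undifferentiated against differentiating RNA (265 genes), with known escape genes in orange, and undifferentiated half-times against position on the X. The pairs follow each other, with Spearman rho 0.74 and 0.67.

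Total nascent transcription from both alleles changed little at 24 h. Xist rose from 1 and 0 allele-assigned reads at 0 h to 363 and 711 (edgeR adjusted p = 4.7e-07, with a fold too uncertain to give over so few reads). Gm15226, a gene model with no known role (166618102 to 166621542), fell from 25.8 ± 3.30 to 8.67 ± 0.37 RPKM (SD, n = 2, log2 change -1.59, SE 0.19, edgeR adjusted p = 0.021). Of 461 X-linked genes those were the only calls, of 16409 autosomal genes 0 passed by edgeR or DESeq2 (1302 genes at unadjusted p under 0.05 by edgeR, 281 by DESeq2), and adjusted over the X alone 37 fell and 3 rose. The X-linked median was -0.44 (1.35-fold lower), with 400 genes below 0, beyond the spread of 0.033 between replicates. Adjusted over the list alone, the constitutive genes Hprt (-0.66, SE 0.16), Pgk1 (-0.80, SE 0.20) and Pdha1 (-0.66, SE 0.18) fell, of 14 measured. In the X-inactivation centre Rlim (-0.94, SE 0.23) and the non-coding RNA gene Ftx (-1.16, SE 0.28), also the 1 escape gene to do so, fell and Xist and Tsix (0.42, SE 0.12) rose, adjusted over the list alone. Gata3 (-1.39, SE 0.45) and Tfap2c (-0.78, SE 0.24), which drive trophectoderm, fell adjusted over the list alone, as did 1 X-linked pluripotency gene and 1 DNA methylation gene, while 1 of the latter list rose. By camera at the preset correlation X-linked genes (adjusted p = 2.0e-24, 0.12 with an estimated correlation), constitutive X-linked genes (4.7e-06, adjusted p = 0.31 with an estimated correlation) and X-linked pluripotency genes (7.4e-04, adjusted p = 0.31 with an estimated correlation) were lower. So were trophectoderm (0.040) and stress response genes (0.036, both adjusted p = 0.63 with an estimated correlation), and the X-inactivation centre was higher, with Xist its largest change (7.2e-08, adjusted p = 0.26 with an estimated correlation, median 0.10, mean 1.64). Gm15226 did not pass without 24 h replicate A (edgeR adjusted p = 0.45) or B (0.98); the total of 2 calls was 6 without 0 h replicate A, 1259 without 0 h replicate B and 1 without either 24 h replicate.

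Total RNA of undifferentiated cells gave a similar account, and the pluripotent state did not change detectably. Xist rose (6.14, SE 0.32, a size limited by the pseudocount at 0 h, limma adjusted p = 4.3e-04), and it was the only call among 11612 genes (90 at unadjusted p under 0.05 by limma; 349 with the replicate series as a block). Nanog was at 534 ± 19.4 RPKM at 0 h and 544 ± 44.6 at 24 h (SD, n = 2), and Nr0b1 at 30.1 ± 4.41 and 29.5 ± 11.7, although its B6 share fell. The X-linked median was -0.39, with 356 of 365 genes below 0, against a spread of 0.27 between replicates. Without 2 h replicate 1 and with the block, 128 X-linked genes fell and 1 rose, with 40 autosomal genes lower and 79 higher. Camera at the preset correlation gave lower X-linked genes (3.8e-63), X-linked constitutive genes (1.0e-07), X-linked pluripotency genes (8.4e-05), escape genes (0.0019), primitive streak genes (2.5e-04) and Wnt targets (0.0015). In the same order, adjusted p = 0.14, 0.29, 0.45, 0.50, 0.14 and 0.14 with an estimated correlation. The X-inactivation centre was higher (0.0019, adjusted p = 0.21 with an estimated correlation, median -0.08, mean 1.03 through Xist). No other list had a member past the threshold, over all genes or adjusted over the list alone. A limit on total X-linked RNA was its ratio to nascent RPKM at 0 h. The log2 ratio, X-linked minus autosomal median, was -0.93 in 0 h replicate 2 and between -1.39 and -0.86 in 11 undifferentiated libraries, but 0.63 in 2 h replicate 1. In the differentiating libraries it ranged from -0.80 (0 h replicate 1) to -1.40 (48 h replicate 1). The limit therefore holds for total X-linked RNA of that course too.

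Of 14 naive pluripotency genes 12 fell and of 12 formative genes 9 rose in differentiating cells at 48 h, though neither list passed by camera with an estimated correlation. The naive factors Prdm14 (51.1 ± 0.98 to 2.1 ± 0.13 RPKM, SD, n = 2, log2 change -4.31, SE 0.057, limma adjusted p = 3.8e-14), Tfcp2l1 (140 to 10.5 RPKM, -3.68, SE 0.068) and Klf4 (46.7 to 3.29 RPKM, -3.64, SE 0.055) fell. Nanog fell from 636 to 104 RPKM (-2.61, SE 0.046). The formative marker Fgf5 rose from 0.126 ± 0.029 to 28.9 ± 0.55 RPKM (SD, n = 2, 5.55, SE 0.066, limma adjusted p = 2.2e-14) and Otx2 from 4.02 to 69.9 RPKM (3.96, SE 0.039). The ERK-induced phosphatase genes Dusp6 (1.23 to 53.2 RPKM, 4.95, SE 0.053) and Dusp4 (0.562 to 33.3 RPKM, 4.99, SE 0.058) rose, and the Wnt target Notum (-4.20, SE 0.065) fell. Other leading genes were the carbonic anhydrase gene Car4 (0.341 to 88.9 RPKM, 6.73, SE 0.049), Enpp3 (6.12), the epithelial splicing regulator Esrp1 (5.15), the keratin gene Krt18 (4.80) and Cldn6 (4.26). On the lower side they were Plagl1 (-4.36), Calcoco2 (-3.86), Mylpf (-3.51), Msln (-3.29) and Jam2 (-3.21). Dnmt3l, a cofactor of de novo DNA methylation, rose from 17.2 to 321 RPKM (4.19, SE 0.036); Aire (4.20) overlaps it, so the value of Aire is uncertain.

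By list, 12 of 14 naive genes fell and 2 rose, Fgf4 (0.57) and Tdgf1 (0.85); Nr0b1 was at -1.0. Camera at the preset correlation gave an adjusted p of 3.3e-04 for this list (adjusted p = 0.38 with an estimated correlation). Of 12 formative genes 9 rose, including the de novo methyltransferase genes Dnmt3a (2.69, SE 0.043) and Dnmt3b (2.40, SE 0.038), and Foxd3 (-0.74) and Zic2 (-0.31) fell (camera 0.011, adjusted p = 0.30 with an estimated correlation). Of 7 core genes 4 fell modestly, such as Pou5f1 (514 to 374 RPKM, -0.46, SE 0.046) and Sox2 (-0.49, SE 0.044), and 3 rose: Utf1 (1.86), Lin28a (1.45) and Dppa4 (1.37). Of 11 ERK targets 9 rose, among them Spry4 (4.13, SE 0.055) and Etv4 (3.62, SE 0.068), while Spry2 (-0.72) and Etv5 (-0.20) fell (camera 0.011, adjusted p = 0.43 with an estimated correlation). Of 10 Wnt targets 7 fell, among them Cdx1 (28.8 to 0.258 RPKM, -5.27, SE 0.077), Sp5 (17.9 to 0.0125 RPKM, -5.17, SE 0.068) and Axin2 (-1.29, SE 0.058). Tcf7 (1.13), Nkd1 (0.71) and Lef1 (0.59) rose (camera 0.030, adjusted p = 0.38 with an estimated correlation). All 4 neuroectoderm genes fell, Tubb3 (-2.74), Nes (-2.36), Map2 and Olig2 (camera 0.011, adjusted p = 0.30 with an estimated correlation). Of 5 primitive streak genes 4 fell, including T (15.8 to 0.564 RPKM, -3.93) and Lefty2 (-2.74), and Eomes rose (1.76). Of 7 primitive endoderm genes 2 rose (Lamb1 1.43, Dab2 0.66) and 3 fell (Lama1 -2.44 among them). Of 6 trophectoderm genes 3 rose (Krt18, Krt8 2.49 and Eomes) and 3 fell (Cdx2 -3.93, Tfap2c -1.69 and Gata3). The 1 two-cell-like gene measured, Zfp352, fell (-1.63). Of 3 fibroblast or feeder markers Thy1 (2.13) and Fbln2 (0.18) rose and Col1a1 fell (-1.27; 1.23 to 0.218 RPKM). The counts adjusted over the list alone were the same for each of these lists.

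Among X-linked genes 236 fell and 76 rose of 357 (limma), with a median of -0.47 (1.39-fold lower) against 0.04 for autosomal genes, of which 4642 fell and 5353 rose of 11863. With no filter on low values 313 X-linked genes fell and 128 rose of 536, with a median of -0.27. Camera gave X-linked genes an adjusted p of 1.3e-06 (adjusted p = 0.30 with an estimated correlation). Of 15 constitutive genes 12 fell, including Prps1 (-1.79, SE 0.037), and Pgk1 (1.14) and G6pdx (0.18) rose (12 and 2 adjusted over the list alone, camera 0.011, adjusted p = 0.30 with an estimated correlation). In the X-inactivation centre 4 of 6 rose (4 adjusted over the list alone): Xist (5.90, SE 0.11), Tsx (1.99), Ftx (1.52) and Rlim (8.10 to 22.1 RPKM, 1.39, SE 0.060). Of 13 escape genes 9 fell and 2 rose (9 and 2 adjusted over the list alone), and of 10 X-linked pluripotency genes 3 fell and 4 rose (2 and 4 adjusted over the list alone).

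**Figure D5:**
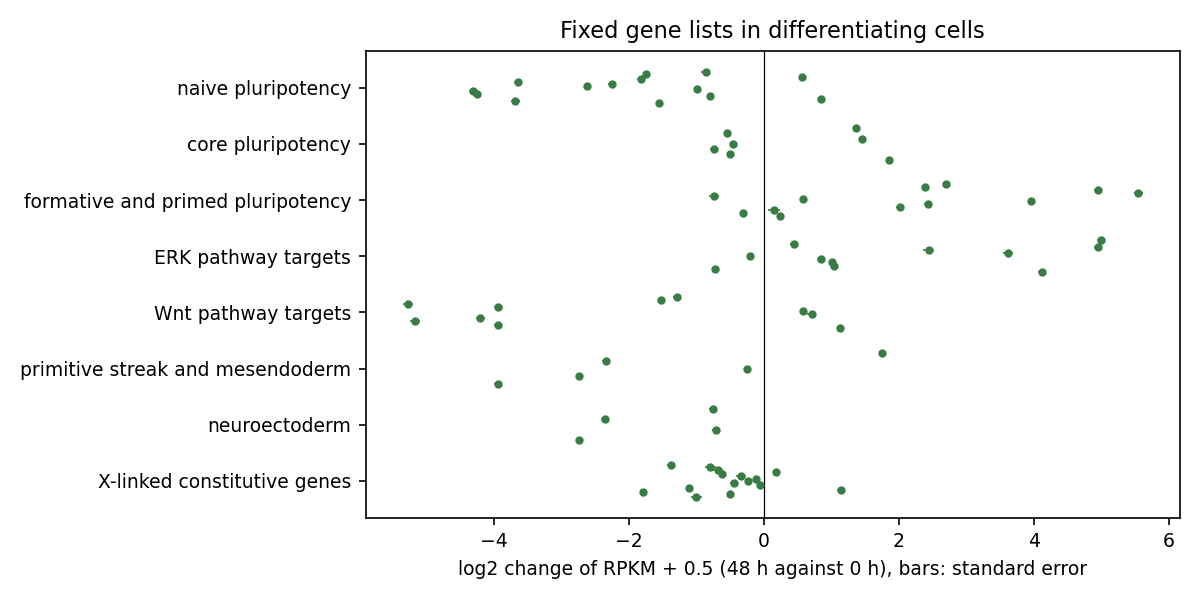
Change of log2(RPKM + 0.5) at 48 h against 0 h in differentiating cells for members of 8 gene lists; points are genes and bars standard errors. Of 14 naive genes 12 lie below 0, and 9 of 12 formative and 9 of 11 ERK target genes rose.

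The fall of naive genes and the rise of formative genes were larger in differentiating than in undifferentiated cells at 24 h. Fgf5 went from 0.126 to 20.8 RPKM in 24 h of differentiation and from 0.0965 to 0.189 in undifferentiated cells (difference 4.88, SE 0.13, limma adjusted p = 9.0e-11). Dusp6 (4.19, SE 0.25), Dusp4 (5.06, SE 0.44) and Dnmt3l (4.18, SE 0.36) were also higher in differentiating cells. Tbx3 (-4.16, SE 0.17, limma adjusted p = 2.1e-09), Tfcp2l1 (-3.34, SE 0.28), Prdm14 (-3.31, SE 0.20), Nanog (-2.65, SE 0.14) and Socs3, a target of LIF signalling (-3.09, SE 0.48), were lower there. Of 14 naive genes 9 were lower and 1 higher (11 and 1 adjusted over the list alone), the higher one being Nr0b1 (1.34, SE 0.39). Camera gave 4.7e-09 at the preset correlation and an adjusted p = 0.0016 with an estimated correlation. Of 12 formative genes 7 were higher (8 adjusted over the list alone, camera 4.7e-09, adjusted p = 8.5e-04 with an estimated correlation). Of 10 ERK targets 4 were higher, including Etv4 (4.95) and Phlda1 (2.26). Of 10 Wnt targets 4 were lower, including Sp5 (-5.15) and Cdx1 (-4.36), and Lef1 (1.92) higher, with the same counts adjusted over the list alone (camera 8.4e-06 and 8.3e-04, adjusted p = 0.011 for both with an estimated correlation). Of 7 primitive streak genes 2 were lower (4 lower and 1 higher adjusted over the list alone), T at -3.41 (camera 0.0056, adjusted p = 0.12 with an estimated correlation). Other leading genes were Pgc (-4.69), Gm694 (-4.59), Aqp3 (-4.09), Stk33 (-3.96) and Plagl1 (-3.00), and Slc7a7 (3.37), Dok2 (3.20), Plcd1 (3.02), Peg10 (2.87), Dnmt3a (2.80), Gja1 (2.65), Plk3 (2.43) and Liph (2.38).

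Among 364 X-linked genes 8 were lower, including Klf8 (-1.76, SE 0.33) and Prps1 (-1.50, SE 0.37), and 12 higher, including the kinase gene Pim2 (3.16, SE 0.56), Tsx (1.24, SE 0.20) and Flna (0.94, SE 0.23). Klf8, Pim2 and Flna were chosen here after their values were seen. Xist itself did not differ detectably (0.19, SE 0.37, limma adjusted p = 0.91). Of 12 escape genes and 21 Xist partners 0 passed over all genes or adjusted over the list alone by limma (2551 of all genes at unadjusted p under 0.05), and 1 of 16 constitutive genes did (Prps1; 1 adjusted over the list alone). Of 11501 autosomal genes 603 were lower and 790 higher. Without 2 h replicate 1 the counts were 36 and 34 on the X and 1379 and 1444 on autosomes, and with the undifferentiated series as a block 20 and 32 on the X and 1340 and 1588 on autosomes. Without differentiating 0 h replicate 1 5 X-linked genes were lower, without differentiating 24 h replicate 1 7 were higher, and without any 1 of the 4 differentiating libraries compared 385 to 401 autosomal genes were lower. The X-linked median of -0.065, within the spread of 0.26, was 0.059 without undifferentiated 24 h replicate 2. At 8 h 1 X-linked gene was lower and 4 higher, with 216 and 253 autosomal genes.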

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

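Of the tests below, the one for a shift of every chromosome and the one for a fuller count of X-linked reads were chosen only after the result was seen. The difference between the RNA courses was tested as an interaction, and each value in the next paragraph is here because that test passed its threshold. Batch and differentiation state cannot be told apart in it, because the title prefixes of the libraries follow the state.

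The B6:Cast ratio changed differently in 24 h for 5 X-linked genes, all lower in differentiating cells, and for 169 autosomal genes that were lower and 181 that were higher. The X-linked genes were Ercc6l (-1.52), Yipf6 (-0.82), Lage3 (-0.76), Vbp1 (-0.57) and Klhl13 (-0.53). Total RNA changed differently for 8 X-linked genes that were lower and 12 that were higher, and for 603 autosomal genes that were lower and 790 that were higher.

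The B6 share of X-linked genes fell after doxycycline in all 3 courses. Loss of the B6 X from part of the cells would lower every X-linked gene alike. Known escape genes fell less than the others by 0.48 on the log2 scale in nascent transcription (two-sided permutation p = 0.02). In undifferentiated RNA (0.45, two-sided permutation p = 0.062) and differentiating RNA (0.47, two-sided permutation p = 0.1) the difference did not pass, so the list alone does not exclude loss there. At 48 h of differentiation, however, Kdm6a changed by 0.01 (SE 0.093) and Rbm3 by -0.39 (SE 0.048) against a median X-linked change of -1.51. These values and those of nascent transcription argue against loss as the whole cause. A shift of every chromosome in the treated libraries is argued against by the autosomes, whose largest median change was -0.0263 of the X-linked one. Silencing by Xist from the B6 X, which the design induces, remains as a hypothesis consistent with these values, found and tested on the same data.

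The 2 h replicate 1 library of the undifferentiated RNA course stood apart in total RNA but not in allelic balance: Rpl10 was at 850 RPKM there and at 16.0 to 22.6 in the other 11 libraries of the course, and Hprt at 189 against 46.5 to 80.2. Its log2 ratio to the other 2 h replicate followed gene length across 10359 genes (Spearman rho -0.49), a pattern that partly degraded RNA or another size selection could give. The median of that ratio, however, was 1.05 over 308 X-linked genes and -0.22 over 10073 autosomal genes. Rbbp7 was at 224 RPKM against 0.740 to 1.92 in the other 11, and Cox7b at 350 against 1.28 to 2.20. Gene length was not compared between X-linked and autosomal genes, so it is not shown to account for that gap. Cells of another genotype are argued against by its autosomal B6 median of 50.9% (50.7 to 51.0% in the others). A few genes taking most reads is argued against by its RPKM sum without the 20 most abundant genes, 309020 against 231143 to 253058. A fuller count of X-linked reads stays open: its X minus autosomal RNA to nascent ratio was 0.63, against -1.39 to -0.86 in the others, which was short of the bound set for it.

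Autosomal allelic ratios changed in the differentiating course, with 2208 calls at 48 h. Gain or loss of whole autosomes is argued against by a largest median change of any autosome of 0.0473 (chromosome 4). Small shifts called only because the replicates were close would not include the 54.0% of calls that exceeded 0.5 on the log2 scale. That share only just passed the bound set, and the pseudocount sets the size of some of these changes. For the other calls, which were smaller, this explanation stays open. Size cannot show whether the larger calls also arose because the replicates, which may be technical, were close. Allelic calls were 1.39 times as frequent among genes whose total RNA changed (23.1%) as among the others (16.6%), short of the bound set. Allelic calls made up 33.8% of genes whose total RNA changed over 2-fold and 19.6% of the rest, a split for which no bound was set, so a link between regulation in differentiation and allelic balance may exist but stays open. Doxycycline alone does not account for the 169 autosomal genes lower and 181 higher in the 24 h difference from undifferentiated cells given the same doxycycline, for example Optn (8.14 to 60.6% against 11.2 to 10.1%). Differentiation, as a biological difference that the design names, was not separated from batch, and 48 h has no undifferentiated counterpart.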

How the results depend on the processing

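The share pseudocounts, RPKM pseudocounts, limma on PRO-seq RPKM, the fits without 2 h replicate 1, the undifferentiated series block in the difference between courses and the left-out libraries of the X share were chosen after seeing the data. Of 143 alternatives to the main results 100 were rated the same, 40 moved and 3 weakened. Of 2153 for other results 1910 were rated the same, 106 moved, 117 weakened, 19 strengthened and 1 reversed. For counts of calls, X shares and half-times the rating judged closeness to the main value, not direction or side of the threshold. Over 831 cases of a named gene with a replicate left out, some genes lost or gained a call. None that passed in either fit turned direction, and a turn in a gene that passed in neither was not counted. DESeq2 was not run on RNA, which has no counts. A fit that left an arm with 1 library assumed that it varied like the others. On simulated data the tests recovered 47% of 2-fold and 82% of 4-fold allelic changes in PRO-seq. The values were 62 and 94% in undifferentiated and 85 and 95% in differentiating RNA. For 2-fold total changes they were 48.5, 23 and 100% in the same order. False calls were 3.39 to 6.59%. Residuals were simulated as independent between libraries, whereas those of undifferentiated RNA correlated within a series. The rates therefore do not describe the real tests of that course or of the difference between courses. The allelic RNA simulation also held fewer genes than the real test, 9654 against 10144 in undifferentiated RNA.

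X-linked genes lower in PRO-seq, 105, numbered 28 to 48 with 1 replicate left out and 30 by DESeq2. The 102 of undifferentiated RNA became 4 to 159 with 1 library left out, 0 with the 2 groups alone (limma, 546 genes at unadjusted p under 0.05) and 161 with the series block. The 265 of differentiating RNA became 118 at a mean RPKM of at least 5, since only 119 X-linked genes were then tested. The 5 that differed between courses became 2 to 38 with 1 library left out and 24 with the block. Calls for total nascent transcription, 2, became 1 to 1259 with 1 replicate left out and 207 with no filter. The 1 call of undifferentiated total RNA became 248 with the block and without 2 h replicate 1. The 1413 total calls between courses became 952 to 2893 with 1 library left out and 2980 with the block, and their X-linked median of -0.065 ranged from -0.18 to 0.059, a reversal. With an estimated correlation 4 list calls remained. Apart from the fewer genes tested, the cause was not tested.

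The X share at 24 h of PRO-seq, 30.4%, was 32.3% from summed reads and 31.7% at 100 reads or more; at 48 h of differentiation, 25.2%, it was 26.8% weighted by RPKM and 26.2% at an RPKM of 5 or more. The PRO-seq half-time of 19.8 h was 20 h by an exponential fit, 12.6 h without the last time, 21.2 h at 100 reads and 19.4 h with autosomal correction. The differentiating one of 32.4 h was 19.5 h by an exponential fit, 16.3 h without the last time and 33.9 h at an RPKM of 5 or more. The rank correlation with level at 0 h missed its threshold in PRO-seq without escape genes (0.11) and in undifferentiated RNA without them (0.12) and at an RPKM of 5 or more (0.15). For these too the cause was not tested.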

Other observations

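The comparisons in this part were planned before the data were examined, while limma replaced the planned edgeR tests of RNA after the data were seen. In differentiating cells at 48 h against 0 h (limma, n = 2 per time point) 84.3% of autosomal genes passed, so calls in both directions are common in any list. By camera at the preset correlation none of the 4 lists that follow passed: adjusted p = 0.95 for DNA methylation, 0.44 for Xist partners, and 0.57 for p53 targets and for the stress response. With an estimated correlation these were 0.97, 0.63, 0.65 and 0.96. Of 10 DNA methylation regulators 4 rose (4 adjusted over the list alone), namely Dnmt3l (4.19, SE 0.036), Dnmt3a, Dnmt3b and the demethylation gene Tet1 (0.37), and 5 fell (5 adjusted over the list alone), among them the demethylation gene Tet2 (13.4 to 2.76 RPKM, -2.09, SE 0.064), Dppa3 (-0.86) and the imprint protector Zfp57 (-0.72). Of 21 Xist partners and silencing factors 7 rose and 10 fell (6 and 10 adjusted over the list alone). The Polycomb cofactor gene Jarid2 (43.2 to 81.4 RPKM, 0.91, SE 0.031) and Ciz1 (1.13) rose, and the RNA methylation gene Wtap (-0.84, SE 0.036) and the Polycomb genes Rnf2 (-0.80) and Eed (-0.76) fell. Spen, which Xist needs for silencing, was at 9.35 ± 0.68 and 8.67 ± 0.91 RPKM (SD, n = 2, -0.10, SE 0.078, limma adjusted p = 0.23).

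Of 11 p53 targets 6 rose and 3 fell (6 and 3 adjusted over the list alone). The pro-apoptotic genes Bbc3 (5.65 to 21 RPKM, 1.81, SE 0.048) and Pmaip1 (1.34) rose, and the cell-cycle inhibitor gene Cdkn1a (80.5 to 44.6 RPKM, -0.85, SE 0.037) fell. Of 12 integrated stress response genes 4 rose and 6 fell (4 and 6 adjusted over the list alone). Ddit4, an inhibitor of mTOR signalling, rose from 36.2 to 225 RPKM (2.62, SE 0.054), and the asparagine synthetase gene Asns fell (338 to 125 RPKM, -1.43, SE 0.033). In the difference between the courses at 24 h Asns was lower in differentiating cells (-2.02, SE 0.18), the 1 of 12 stress genes past the threshold (1 adjusted over the list alone). No member of the p53, stress, methylation or Xist partner lists passed in undifferentiated total RNA.

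Some pluripotency genes shifted their allelic balance in differentiating RNA at 48 h. Zfp42 went from 15.8 to 30.3% B6 (log2 change 1.16, SE 0.050) and Dppa5a from 43.1 to 65.1% (1.27, SE 0.026), while Klf4 went from 52.0 to 34.8% (-1.0, SE 0.080). Otx2 went from 8.90 to 32.0% (2.16, SE 0.10). Of 14 naive genes 4 shifted toward B6 and 6 away from it, 1 of them the X-linked Nr0b1 (5 and 6 adjusted over the list alone), of 7 core genes 5 rose and 2 fell (5 and 2 adjusted over the list alone), and of 10 formative genes 4 rose and 1 fell (4 and 1 adjusted over the list alone).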
